A study of Mus musculus with 18 samples.

How the data were processed

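Polyadenylated RNA from mouse liver was sequenced in 18 libraries. The mice were C57BL/6J, and the libraries formed 6 groups of 3: each of 3 ages (2, 8 and 16 weeks) had a group injected with asparaginase and a group injected with PBS. Each library was treated as 1 mouse, although 3 of the 2-week libraries hold transcripts of both sexes. Asparaginase, the leukaemia drug that removes asparagine from the blood, was given at 3 IU per g of body weight once a day, with 7 injections at 2 and 16 weeks and 8 injections at 8 weeks. Per the labels' protocols the last injection fell at about 8 AM and liver was taken 7.5 h later, and the RNA of all 3 ages went to library preparation and sequencing together. The 8-week libraries are also part of another series, per the labels. Libraries are named here by age, treatment and replicate; replicate numbers follow the order of deposition and pair no mice. By their labels every group held both sexes, with 1 mouse of the rarer sex in each; the transcripts of 3 libraries of 2 weeks go against this.

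The values are gene counts, whole numbers per gene and library that the authors deposited in 1 table of 37315 genes, of which 25426 had at least 1 count. Per the submitters' processing notes, TopHat2 2.0.9, TopHat and DESeq2 were used with the builds named GRCm38 and mm10; their roles are not stated there. The read counter, the gene annotation and the use of strand in counting are not given in the sources used here. Counts per library, as deposited by the authors, totalled between 24690871 and 46949361, which sets the precision for genes of low level: intervals and floors printed for such genes cover counting error only. No pair of columns was identical (0 pairs). Gene symbols and GRCm38 positions were taken by gene identifier from GENCODE release M21, which matched 35449 of the 37315 identifiers.

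All tests started from the deposited counts. Genes were kept by edgeR's filterByExpr over the 6 groups with its minimum count of 10 and minimum total of 15, which left 16213 genes. Library sizes were scaled by TMM, and a quasi-likelihood negative binomial model (edgeR 4.0.16, R 4.3.3) was fitted to all 18 libraries with 1 term per group and a sex term within each age, coded 0.5 for males and -0.5 for females, so that each comparison refers to an even mix of the labelled sexes. The model had 9 residual degrees of freedom, a median of 3.7 prior degrees of freedom and a common dispersion of 0.0411. The comparisons were asparaginase against PBS at each age, the mean of those 3 effects, the differences of the effects between ages and their joint test, and the ages against each other in PBS mice. P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene is said to have risen or fallen at an adjusted p under 0.05. All adjusted p-values of single genes come from this edgeR test unless another tool is named. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. Levels are CPM (counts scaled to a common library total) on TMM-scaled library sizes, given as mean ± SD of 3 libraries. A fold against a group with 0 counts in all of its libraries was computed against a floor of 3 counts over the group and is a lower bound; with 1 to 3 counts the ratio of counts is given with its exact 95% interval.

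Gene lists were written by hand for amino acid stress, liver metabolism, secreted proteins, immunity, sex and age biased genes and the cell types of liver and nearby organs. Of 1071 entries in 39 lists, 1062 were matched, and 38 lists were tested. Counts of list members come from the gene test over all genes tested, with the count adjusted over the list alone beside it. Lists were tested with camera on voom values (limma 3.58.1) with its preset correlation of 0.01 between genes, with camera and an estimated correlation, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. The adjusted p of a list covers the 38 lists of one comparison.

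Genes named in the text were taken by a fixed rule, and not every gene it took is printed. For each effect of asparaginase these are Asns, Atf4, Atf5, Ddit3, Trib3, Fgf21, Ppp1r15a and Sesn2, the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 1 CPM in the higher group, and members of the lists described, taken by smallest p. For differences between ages and for the mean effect, genes were taken by smallest p, 8 in each direction for the mean. For the ages in PBS mice the 5 largest changes each way were taken. Predicted genes without a common symbol and immunoglobulin and T-cell receptor segments were passed over. The list members named for the mean effect and for the ages were chosen after their values were seen. So were the lists described there, the genes shared between ages, the sex-biased genes, the markers of other tissues, and Saa1 and Saa2.

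Of the 160 genes named by the rule, 40 overlap exons of another annotated gene, and 2 of them, Gpat3 and Tuba4a, share at least 20% of their exon bases with a gene that was tested, Gpat3 with an antisense gene. As the use of strand is not given in the sources used here, the values of these 2 genes are uncertain. The Mup genes (21 in the table), Hamp and Hamp2, the amylases, the Sult2a genes, the Cyp4a genes and other close paralogs can share reads, and how the authors' counting divided such reads is not known; values of single members are uncertain.

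The design, the tests, the gene lists, the naming rule and a first set of alternatives were fixed before the data were examined. That set held no sex term, 1 sex term for all ages, DESeq2 1.42.0 with the same design, limma-voom, median-of-ratios and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, each age alone, a threshold of 0.01, a 2-fold minimum, and leaving out each library in turn. Further alternatives were chosen after seeing the data: a sex term in adults only, leaving out 3 libraries of 2 weeks that hold both female and male transcripts, leaving out 2 libraries of 8 weeks that hold transcripts of squamous epithelium, leaving out the Mup genes, and the lists without each library. A library counts as holding both sexes above 50 CPM of Xist and 10 CPM of Ddx3y, and as holding squamous transcripts above 100 CPM summed over 12 markers; both limits were also set after seeing the data. Other splits of the same mice into groups of the same sizes were run for every count, 60 draws for the joint comparisons, a number chosen for run time.

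The pipeline was tested on simulated counts for each age, with 100 genes changed by 1 and 100 genes changed by 2 on the log2 scale. Of the smaller changes, 66, 65 and 58 were recovered at 2, 8 and 16 weeks, and of the larger ones 88, 92 and 89, among 15921, 15848 and 15916 genes tested. Of the unchanged genes 6, 17 and 5 were called, which is 3.8%, 9.8% and 3.3% of the calls. Counts were drawn independently for each gene and library, so shifts shared by many genes within a library were not simulated. These rates need not hold for the real libraries.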

Results

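Gene counts were compared in 18 libraries of liver from C57BL/6J mice. At each of 3 ages, 2, 8 and 16 weeks, 3 libraries came from mice given daily injections of asparaginase and 3 from mice given PBS. The design asks what repeated depletion of asparagine does to gene expression in liver, and whether the response depends on the age of the animal. Total counts at 2 weeks were 26507374, 27263553 and 26928605 in the PBS libraries (replicates 1 to 3) and 28208257, 27465238 and 28491923 in the asparaginase libraries. At 8 weeks they were 36173744, 44371476 and 39223007 with PBS and 35651152, 43622389 and 37365243 with asparaginase. At 16 weeks they were 35862867, 37852333 and 45358073 with PBS and 36544093, 46949361 and 24690871 with asparaginase. The major urinary protein (Mup) genes took between 0.05% and 0.58% of the counts in the 2-week libraries and between 5.39% and 47.91% in the adult libraries.

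Xist, the transcript of the inactive X chromosome, and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) matched the labelled sex in 15 of the 18 libraries. The other 3 were 2-week libraries that held both. Xist stood at 263 and 361 CPM in PBS replicates 1 and 2, both labelled male, beside 52.4 and 57.3 CPM summed over the Y-linked genes. In asparaginase replicate 3, labelled female, Xist stood at 279 CPM and the Y-linked sum at 57.0 CPM. The unmixed 2-week female libraries held 540 and 617 CPM of Xist, and the unmixed male library held 126 CPM of the Y-linked genes. The sex term at 2 weeks therefore rests on labels that 3 of its 6 libraries contradict in part.

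**Figure D1:**
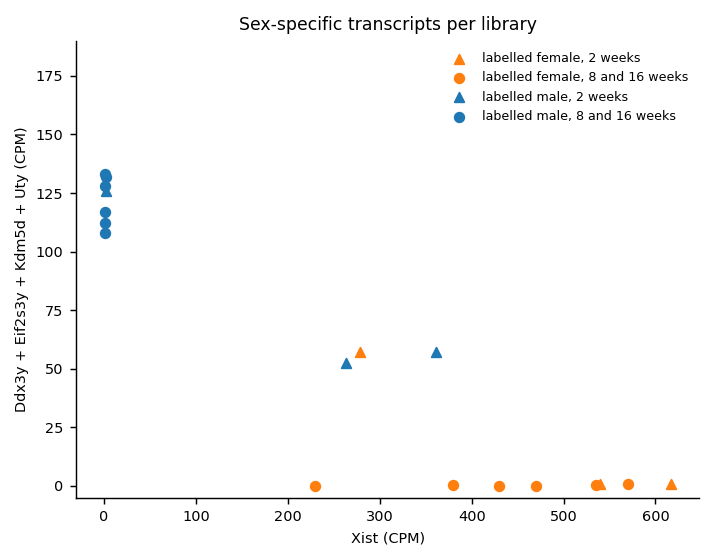
Xist level (CPM) against the summed level of Ddx3y, Eif2s3y, Kdm5d and Uty (CPM), 1 point per library, marked by labelled sex and by age (2 weeks or adult). In 15 libraries only 1 of the 2 quantities is high, and 3 libraries of 2 weeks lie between, with Xist from 263 to 361 CPM and Y-linked sums from 52.4 to 57.3 CPM.

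Some libraries also held transcripts of other tissues. The sum over 12 markers of stratified squamous epithelium was 765 and 412 CPM in 8-week asparaginase replicates 1 and 2 and 8.78 CPM in replicate 3. The 8-week PBS libraries held 5.2, 0.265 and 0.425 CPM, and the highest PBS library, replicate 3 of 2 weeks, held 65.1 CPM. Pancreatic acinar transcripts summed to 2010, 3070 and 1090 CPM in the 2-week asparaginase libraries and to 349 CPM at most in the 2-week PBS libraries. At 16 weeks the acinar sum was 7190 CPM in asparaginase replicate 3, 586 CPM in replicate 1, and 1000 and 1130 CPM in PBS replicates 2 and 3. The sum over 10 skeletal muscle genes was 173, 328 and 54.4 CPM in the 16-week PBS libraries against 6.33, 24.3 and 4.34 CPM in the 16-week asparaginase libraries, so at that age muscle transcripts moved with treatment. At 8 weeks it was 800, 371 and 1030 CPM with PBS and 2820, 447 and 188 CPM with asparaginase, higher in each of the 3 female libraries than in each of the 3 male ones. The main tests did not choose or weight libraries by these levels.

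**Figure D2:**
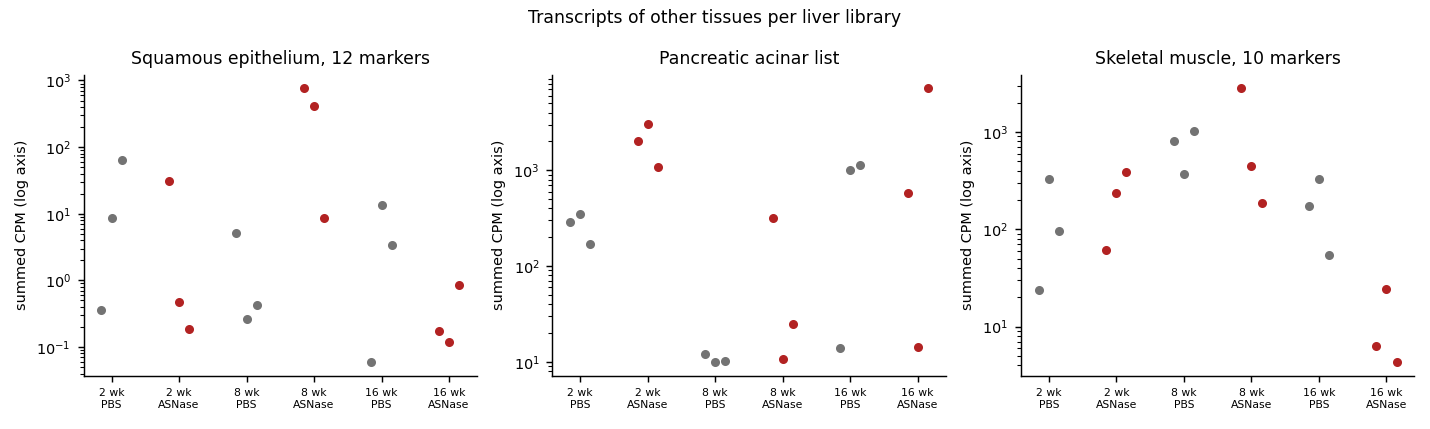
Summed level (CPM, log axis) of 12 squamous epithelial markers, of the pancreatic acinar list and of 10 skeletal muscle genes, 1 point per library, by age and treatment. The squamous sum is 765 and 412 CPM in 2 of the 8-week asparaginase libraries and at most 65.1 CPM in the PBS libraries, and the acinar sum reaches 7190 CPM in 1 of the 16-week asparaginase libraries.

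At 2 weeks asparaginase raised genes of the amino acid response. Asns, asparagine synthetase (chromosome 6, 7675169 to 7693254, GRCm38), stood at 25.5 ± 5.72 CPM (mean ± SD, n = 3) with asparaginase and at 3.70 ± 0.233 CPM with PBS, a log2 fold change of 2.85 (SE 0.22). The pseudokinase Trib3 rose by 2.96 (SE 0.41) on the log2 scale, the transcription factor Atf5 by 2.08 (SE 0.32), the stress regulator Nupr1 by 2.92 (SE 0.44), and Psat1, which makes phosphoserine in serine synthesis, by 1.74 (SE 0.27). Hamp, which encodes the iron hormone hepcidin, rose by 4.81 (SE 0.53), from 1.36 ± 0.262 to 39.4 ± 51.6 CPM, and its paralog Hamp2 by 3.81 (SE 0.58). The exostosin family gene Extl1 rose by 3.77 (SE 0.41). The falls included C9, a pore-forming complement component, at -1.92 (SE 0.30), from 37.8 ± 7.03 to 11.6 ± 4.53 CPM, and the cell cycle transcription factor E2f1 at -1.39 (SE 0.24). Also lower were the tubulin-binding gene Stmn1 at -1.18 (SE 0.18), the chromatin remodeller Hells at -1.17 (SE 0.23), the steroid dehydrogenase gene Akr1c18 at -1.39 (SE 0.22) and the small GTPase gene Mras at -0.87 (SE 0.16). The largest fold belonged to the vomeronasal receptor gene Vmn2r3 (chromosome 3, 64257215 to 64289709), at 22.37, 6.69 and 2.57 CPM in the asparaginase libraries and at most 0.11 CPM in PBS, a log2 fold change of 8.39 (SE 1.32). All 3 asparaginase libraries lay beyond all 3 PBS libraries for each of these genes.

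Of the 41 measured genes in the ATF4 and CHOP target list, 9 rose at 2 weeks and 0 fell (17 rose adjusted over the list alone), with Asns, Trib3, Atf5 and Nupr1 among them. The list was higher than other genes by camera (adjusted p = 3.41e-15), a call lost at adjusted p = 0.0791 with an estimated correlation, while fry gave adjusted p = 0.00325. Fgf21, a hepatokine of amino acid stress, stood at 17.5 ± 16.9 CPM against 1.67 ± 0.836 CPM but missed the threshold (log2 3.35, SE 0.70, adjusted p = 0.0608). So did Ddit3 (1.12, SE 0.29, adjusted p = 0.115), Sesn2 (0.58, adjusted p = 0.292), Atf4 (0.21, adjusted p = 0.658) and Ppp1r15a (0.21, adjusted p = 0.79). Of 40 cell cycle genes, E2f1 alone fell over all genes tested, and 33 fell adjusted over the list alone (median log2 -1.09). The camera adjusted p of this list was 7.97e-36, and the call was lost at adjusted p = 0.0791 with an estimated correlation (fry adjusted p = 0.00565). The summed cell cycle list stood at 209, 349 and 312 CPM with asparaginase and at 496, 469 and 535 CPM with PBS. None of 75 ribosomal protein genes passed over all genes (0 by edgeR), and 58 rose adjusted over the list alone (median 0.44, camera adjusted p = 1.2e-32, adjusted p = 0.537 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, Sars rose by 0.82 (SE 0.16) and 3 rose adjusted over the list alone (adjusted p = 0.000605, and adjusted p = 0.668 with an estimated correlation). Single members of other lists also rose: Slc38a7 of 23 amino acid transporters (0.45, SE 0.08), the mitochondrial chaperone Hspa9 of 20 heat shock genes (0.76, SE 0.13), the bile phospholipid transporter Abcb4 of 30 bile acid genes (0.73, SE 0.11) and Cyp3a44 of 36 drug-metabolizing cytochromes (1.63, SE 0.27). Adjusted over the list alone 1, 1, 2 and 3 rose in these lists, and camera found no shift in any of the 4 (adjusted p = 0.291, 0.319, 0.916 and 0.874). Hamp was the 1 riser of 29 acute phase genes (3 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.143), and C9 the 1 faller of 24 complement genes (1 adjusted over the list alone). By camera the adjusted p was 0.00535, and it was lost at adjusted p = 0.668 with an estimated correlation. The cholesterol synthesis list had a median of -1.59 with 0 of 25 genes past the threshold. Its summed level was 6060 CPM in PBS replicate 1 against 746 to 1440 CPM in the other 2-week libraries. Its camera call (adjusted p = 5.55e-13, adjusted p = 0.537 with an estimated correlation) was lost without that library (adjusted p = 0.179).

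In all, 53 genes rose and 17 fell at 2 weeks among 16213 tested, 2043 genes had an unadjusted p under 0.05, and in 67 of the 70 the asparaginase and PBS libraries separated completely. Chance alone would separate 10% of unselected genes, but the 70 were selected for their difference between these libraries, so neither this count nor those given for the other comparisons is separate evidence. DESeq2 called 228 up and 224 down and limma-voom 169 genes. The count depended on single libraries: it was 0 without 2-week asparaginase replicate 1, and 26, 15 and 144 without 2-week PBS replicates 1, 2 and 3. It was 265 without 8-week PBS replicate 1, 42 without 8-week asparaginase replicate 2, 37 and 45 without 16-week PBS replicates 1 and 2, and 40 and 41 without 16-week asparaginase replicates 1 and 2. Without the 3 mixed libraries, fitted with a sex term in adults only, 0 genes passed, in a fit that keeps 1 PBS library of 2 weeks.

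At 8 weeks Asns, Psat1, Mthfd2, Phgdh and Pck2 were among the genes that rose. Asns stood at 8.78 ± 5.09 CPM with asparaginase and at 1.92 ± 1.75 CPM with PBS (n = 3 each), a log2 fold change of 1.80 (SE 0.24). Psat1 rose by 2.05 (SE 0.34), the mitochondrial folate enzyme Mthfd2 by 1.95 (SE 0.33), Phgdh, the entry enzyme of serine synthesis, by 2.17 (SE 0.41), and Pck2, mitochondrial phosphoenolpyruvate carboxykinase, by 1.00 (SE 0.14). The metallothioneins Mt1 and Mt2 rose by 3.07 (SE 0.54) and 3.70 (SE 0.67), with Mt1 at 487.44 CPM in replicate 1 and at 68.82 and 60.64 CPM in replicates 2 and 3. The interferon-inducible GTPases fell: Igtp by 1.45 (SE 0.22), Ifi47 by 1.40 (SE 0.19), Tgtp1 by 1.51 (SE 0.28) and Irgm1 by 0.95 (SE 0.17) on the log2 scale. Among other falls were Hdhd3, which fell by 1.46 (SE 0.25), and Insc by 1.55 (SE 0.29).

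Of the 6 largest rises named at 8 weeks, 5 belonged to Aloxe3, Pof1b, Acsbg1, Evpl and Dsg1a, genes known from epidermis or other epithelia, and the other to Mt2. No list of such genes was tested. The envoplakin gene Evpl rose by 4.51 (SE 0.75), the desmoglein gene Dsg1a by 3.41 (SE 0.60), Pof1b by 5.48 (SE 0.97) and Acsbg1 by 4.92 (SE 0.90), while Aloxe3 had a ratio of counts of 66.9 (95% interval 18.2 to 558). Of the 31 genes that rose, 11 were no higher in replicate 3 than in the highest 8-week PBS library, among them Aloxe3, Acsbg1, Phgdh, Mt2, the interleukin-1 receptor antagonist Il1rn (1.59, SE 0.27) and the p53 target Phlda3 (1.32, SE 0.23). Without the 2 libraries that held squamous transcripts 0 genes passed at 8 weeks by edgeR, but that fit keeps 1 asparaginase library of this age, a male one, and the loss of replicates alone can end the calls.

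In the ATF4 and CHOP target list 5 of 41 genes rose and 0 fell (9 rose adjusted over the list alone), Asns, Psat1, Mthfd2 and Pck2 among them, with a camera adjusted p of 3.48e-05 and an adjusted p = 0.335 with an estimated correlation. Trib3 stood at 27.9 ± 1.34 CPM against 7.99 ± 3.39 CPM and missed the threshold (log2 1.77, SE 0.40, adjusted p = 0.0627). Fgf21 (2.61, SE 0.83, adjusted p = 0.131), Atf5 (0.16, adjusted p = 0.847), Ddit3 (0.19, adjusted p = 0.79), Sesn2 (0.42, adjusted p = 0.364), Atf4 (0.18, adjusted p = 0.585) and Ppp1r15a (-0.05, adjusted p = 0.927) did not pass. Of 30 serine, glycine and one-carbon genes 3 rose, Psat1, Mthfd2 and Phgdh (5 rose and 1 fell adjusted over the list alone). The list's median was -0.07 and its mean 0.24, and camera found no shift (adjusted p = 0.969). Of 40 interferon response genes 5 fell and 0 rose (19 fell adjusted over the list alone, median -0.64), at a camera adjusted p of 2.66e-17 and an adjusted p = 0.335 with an estimated correlation. None of 32 endoplasmic reticulum chaperone genes passed over all genes (0 by edgeR), and 15 fell adjusted over the list alone. With camera the adjusted p came to 4.73e-11, and it was lost at adjusted p = 0.335 with an estimated correlation. The Kupffer cell list had 0 of 22 genes past the threshold, with 13 lower and 1 higher adjusted over the list alone. The adjusted p by camera was 2.07e-08, and it was lost at adjusted p = 0.335 with an estimated correlation. In the acute phase list Mt1, Mt2 and Il1rn rose and no other of 29 genes passed. Its median was -0.10, its mean 0.09 and its camera adjusted p 0.86.

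At 8 weeks 31 genes rose and 28 fell, 2989 had an unadjusted p under 0.05, and in 43 of the 59 the groups separated completely. DESeq2 called 339 up and 320 down, and limma-voom called 53. The count was 0 without 2-week PBS replicate 2, 2-week asparaginase replicate 2, 8-week PBS replicate 3, 16-week PBS replicate 2, 8-week asparaginase replicate 1 or 16-week asparaginase replicate 1. It was 1 without 16-week PBS replicate 1, 4 without 16-week asparaginase replicate 2, 7 without 16-week PBS replicate 3 or 16-week asparaginase replicate 3, 8 without 2-week asparaginase replicate 3, 15 without 8-week PBS replicate 1 and 32 without 8-week asparaginase replicate 2. It rose to 114 without 8-week PBS replicate 2, 159 without 2-week PBS replicate 1 and 398 without 8-week asparaginase replicate 3. Without the 3 mixed 2-week libraries and with a sex term in adults only it was 0, and no gene passed an adjusted p of 0.01 (0 by edgeR).

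At 16 weeks Psat1, Asns, Mthfd2 and Phgdh were among the genes that rose. Psat1 (chromosome 19, 15904678 to 15947337) stood at 19.1 ± 1.49 CPM with asparaginase and at 0.570 ± 0.104 CPM with PBS (n = 3 each), a log2 fold change of 5.11 (SE 0.35). Asns stood at 23 ± 8.52 CPM against 0.936 ± 0.502 CPM (4.27, SE 0.26). Mthfd2 rose by 3.66 (SE 0.34), Phgdh by 3.66 (SE 0.39), Extl1 by 3.14 (SE 0.37), Atf5 by 2.03 (SE 0.33) and Pck2 by 1.80 (SE 0.14). Cxcl13, the chemokine that draws B cells, rose by 2.52 (SE 0.27), from 3.33 ± 1.07 to 17.4 ± 0.267 CPM, and the macrophage scavenger receptor gene Marco by 2.49 (SE 0.33). Among the falls were the transferrin receptor gene Tfrc at -1.69 (SE 0.27), from 29.3 ± 3.70 to 9.24 ± 0.607 CPM, and the sterol transporter gene Abcg5 at -0.87 (SE 0.14). Other falls were those of the endoplasmic reticulum chaperone gene Hsp90b1 at -0.79 (SE 0.14), Arhgef37 at -1.12 (SE 0.19), Hip1r at -0.73 (SE 0.12) and the alpha-tubulin gene Tuba4a at -0.94 (SE 0.16).

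Of the 41 ATF4 and CHOP targets 7 rose and 0 fell at 16 weeks (15 rose adjusted over the list alone), at a camera adjusted p of 3.29e-16, an adjusted p = 0.0712 with an estimated correlation and a fry adjusted p of 0.00284. Fgf21 stood at 13.1 ± 10.1 CPM against 0.544 ± 0.387 CPM and missed the threshold (4.31, SE 0.86, adjusted p = 0.0777). So did Trib3 (2.01, SE 0.40, adjusted p = 0.072), Sesn2 (1.10, SE 0.23, adjusted p = 0.0833), Ddit3 (0.54, adjusted p = 0.532), Ppp1r15a (0.23, adjusted p = 0.725) and Atf4 (0.00, SE 0.16, adjusted p = 1). Psat1, Mthfd2 and Phgdh rose in the serine, glycine and one-carbon list (3 of 30, and 5 adjusted over the list alone). Tested with camera, the list had an adjusted p of 0.0329 (adjusted p = 0.524 with an estimated correlation). The glycyl-tRNA synthetase gene Gars rose by 0.98 (SE 0.12), 1 of 20 cytosolic synthetases and 8 adjusted over the list alone. As a list they had a camera adjusted p of 6.77e-06 (adjusted p = 0.462 with an estimated correlation). Among 29 acute phase genes the serpin gene Serpina3n rose by 1.37 (SE 0.15) and Itih4 by 0.89 (SE 0.14), and 11 rose and 1 fell adjusted over the list alone. By camera the adjusted p was 1.45e-07, with an adjusted p = 0.212 with an estimated correlation and a fry adjusted p of 0.0422. Saa1 and Saa2, named outside the rule, were higher in every asparaginase library of 16 weeks than in every PBS one. Saa1 stood at 760.62, 733.52 and 357.92 CPM against 26.67, 38.57 and 35.81 CPM. Saa2 stood at 630.51, 585.55 and 340.42 CPM against 17.83, 16.53 and 16.42 CPM. At 8 weeks Saa1 stood at 20.1, 37.94 and 9.97 CPM against 35.36, 22.19 and 11.16 CPM. No fold change or test is given for them. Hsp90b1 was the 1 faller of 32 endoplasmic reticulum chaperone genes, of which 17 fell adjusted over the list alone. Camera gave an adjusted p of 1.71e-14 (adjusted p = 0.391 with an estimated correlation). Csad, a taurine synthesis enzyme, rose by 1.48 (SE 0.25) in the list of urea cycle and amino acid breakdown, and the oxysterol hydroxylase gene Cyp39a1 by 1.45 (SE 0.25) in the bile acid list; for each, 2 of the 3 asparaginase libraries lay above all PBS libraries. The first list had a camera adjusted p of 7.91e-09 and an adjusted p = 0.428 with an estimated correlation, the second 0.00508 and an adjusted p = 0.44 with an estimated correlation. Tfrc was the 1 faller of 13 erythroid genes (camera adjusted p = 0.0146, adjusted p = 0.462 with an estimated correlation) and Marco the 1 riser of 22 Kupffer cell genes (camera adjusted p = 0.1). No cell cycle gene passed over all genes (0 of 40 by edgeR), and 13 rose and 1 fell adjusted over the list alone. By camera the adjusted p was 3.33e-05 (adjusted p = 0.474 with an estimated correlation).

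At 16 weeks 31 genes rose and 7 fell, 1842 had an unadjusted p under 0.05, and the groups separated completely in 36 of the 38. DESeq2 called 150 up and 172 down, and limma-voom called 38. The count was 5 without 16-week asparaginase replicate 3, 21 without asparaginase replicate 1, and 17, 21 and 8 without 16-week PBS replicates 1, 2 and 3.

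**Figure D3:**
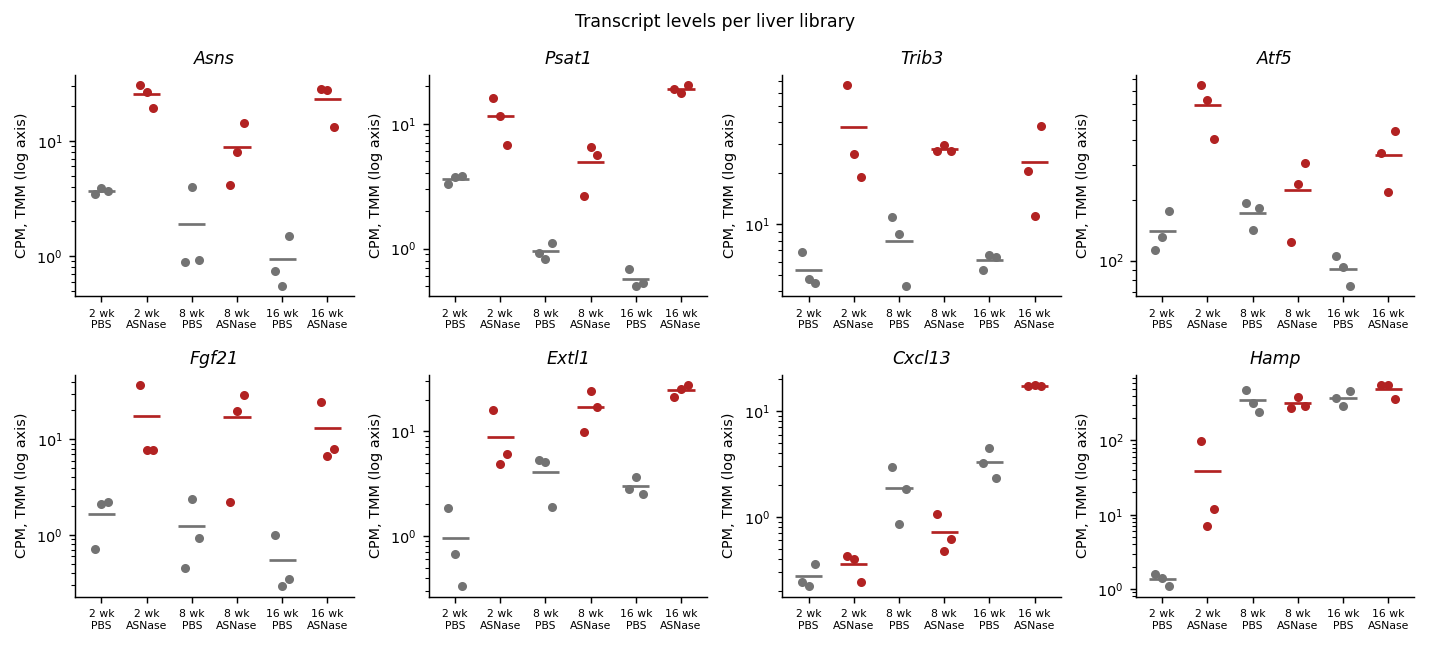
Level (CPM on TMM-scaled library sizes, log axis) of Asns, Psat1, Trib3, Atf5, Fgf21, Extl1, Cxcl13 and Hamp, 1 point per library by age and treatment, with a bar at each group mean. Asns is higher in every asparaginase library than in every PBS library of its age, at 25.5 against 3.70 CPM at 2 weeks, 8.78 against 1.92 CPM at 8 weeks and 23 against 0.936 CPM at 16 weeks.

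Asns and Psat1 rose at all 3 ages, the 2 genes called at each. Neither was called at all 3 with no sex term (Asns adjusted p = 0.0849 at 2 weeks and 0.118 at 8 weeks, Psat1 0.0702 at 2 weeks) or with each age fitted alone (Asns 0.148 at 8 weeks, Psat1 0.161 and 0.148 at 2 and 8 weeks). Of the 18 fits that left out 1 library, Asns passed in 17, 11 and 18 at 2, 8 and 16 weeks and Psat1 in 14, 5 and 18. At 2 and 16 weeks 10 genes rose at both, where independent lists would share 0.101: Asns, Psat1, Atf5, Extl1, the phosphatase gene Alpl, the pyrophosphate transporter gene Ank, the acyltransferase genes Gpat3 and Soat2, Arhgef2 and Gramd1c. At 8 and 16 weeks 5 rose at both (expected 0.059): Asns, Psat1, Phgdh, Mthfd2 and Pck2. At 2 and 8 weeks 4 rose at both (expected 0.101), Pabpc4 and a predicted gene besides Asns and Psat1. Shared falls numbered 3 at 2 and 8 weeks (Ppil1 and 2 predicted genes), 1 at 8 and 16 weeks (Tuba4a) and 0 at 2 and 16 weeks. Across all genes, which are not independent replicates, Spearman's rho of the log2 fold changes was 0.25 between 2 and 8 weeks, 0.24 between 2 and 16 weeks and 0.16 between 8 and 16 weeks. In total 19 genes were called in the same direction at 2 or more ages. That number was 3 without 16-week PBS replicate 3 or asparaginase replicate 3, 4 without 2-week PBS replicate 2, 5 and 6 without 16-week PBS replicates 1 and 2, and 6 without 16-week asparaginase replicate 1. It was 9 and 10 without 2-week asparaginase replicates 1 and 2, 10 without 16-week asparaginase replicate 2, 11 without 8-week PBS replicate 3 and 29 without 8-week asparaginase replicate 3. It was 0 without the 3 mixed libraries (with a sex term in adults only) and 9 without the 2 that held squamous transcripts, fits that each keep 1 library in a group.

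Averaged over the 3 ages (9 libraries per treatment), the test has more power than at any single age, and its larger count of calls is not a sign of a larger effect. The 8 rises of smallest p were Asns (2.97, SE 0.14), Psat1 (2.97, SE 0.19), Pck2 (1.08, SE 0.08), Extl1 (2.88, SE 0.22), Ank (1.10, SE 0.09), Gpat3 (1.80, SE 0.16), Mthfd2 (2.01, SE 0.19) and Phgdh (2.27, SE 0.22). Fgf21 rose by 3.42 (SE 0.46), Trib3 by 2.25 (SE 0.23), Atf5 by 1.43 (SE 0.20) and the stress sensor gene Sesn2 by 0.70 (SE 0.13). Ddit3 (0.61, SE 0.17, adjusted p = 0.0588), Atf4 itself (0.13, SE 0.09, adjusted p = 0.426) and Ppp1r15a (0.13, SE 0.12, adjusted p = 0.567) did not pass. Among the falls of smallest p were Hip1r (-0.57, SE 0.07), the glycolate oxidase gene Hao1 (-0.63, SE 0.08), Maged1 (-0.45, SE 0.06), the nuclear import gene Kpna2 (-0.45, SE 0.06), the sulfate donor synthase gene Papss1 (-0.44, SE 0.06), C9 (-1.16, SE 0.16) and Pid1 (-0.50, SE 0.07).

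In the mean effect 19 of 41 ATF4 and CHOP targets rose and 0 fell (25 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 5.33e-16, an adjusted p = 0.0732 with an estimated correlation and a fry adjusted p of 0.000111. Of 30 serine, glycine and one-carbon genes 6 rose and 0 fell (7 and 3 adjusted over the list alone), the mitochondrial folate enzyme Aldh1l2 by 2.24 (SE 0.31) besides Psat1, Mthfd2 and Phgdh. Its median was -0.04, its mean 0.31 and the camera adjusted p 0.599. Amino acid transporters rose in 4 of 23 cases (5 adjusted over the list alone), the cationic carrier gene Slc7a1 by 1.26 (SE 0.22), and Slc38a7 by 0.27 (SE 0.04). The paired subunit genes Slc7a5 rose by 0.49 (SE 0.11) and Slc3a2 by 0.48 (SE 0.12). With camera the adjusted p came to 0.0144, and adjusted p = 0.493 with an estimated correlation. The synthetase genes Gars (0.53, SE 0.07), Sars (0.52, SE 0.09) and Iars (0.30, SE 0.07) rose, 3 of 20 and 5 adjusted over the list alone. With camera the adjusted p came to 0.0433, and it was lost at adjusted p = 0.722 with an estimated correlation. Ribosomal protein genes rose in 3 of 75 cases (20 adjusted over the list alone), Rplp0 by 0.37 (SE 0.09), Rps12 by 0.36 (SE 0.09) and Rpl10a by 0.33 (SE 0.09), at a camera adjusted p of 6.88e-17 and an adjusted p = 0.521 with an estimated correlation. Of 19 pancreatic acinar genes 1 rose and 0 fell (19 rose adjusted over the list alone). Their camera adjusted p was 8.39e-05, and it was lost at adjusted p = 0.601 with an estimated correlation. Only at 2 weeks did the acinar sum lie higher in every asparaginase library than in every PBS one. At 16 weeks it was 586, 14.4 and 7190 CPM with asparaginase and 13.8, 1000 and 1130 CPM with PBS.

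Among the genes that fell were members of the interferon response and of protein folding. Of 40 interferon response genes 17 fell and 0 rose (33 fell adjusted over the list alone, median -0.52), among them Irgm1 (-0.74, SE 0.10), Igtp (-0.90, SE 0.13) and Ifi47 (-0.69, SE 0.11). The adjusted p by camera was 5.3e-21, with an adjusted p = 0.493 with an estimated correlation and a fry adjusted p of 0.0366. Lists of immune cells were lower as well by camera: 0 of 20 T and NK cell genes passed (0 adjusted over the list alone; adjusted p = 0.0027, adjusted p = 0.493 with an estimated correlation) and 0 of 13 B cell genes (5 fell adjusted over the list alone; adjusted p = 0.00239, adjusted p = 0.493 with an estimated correlation). Of 22 Kupffer cell genes 2 fell and 1 rose, as adjusted over the list alone (camera adjusted p = 0.0177, adjusted p = 0.659 with an estimated correlation). A change in cell make-up was not separated from a change of the interferon genes within cells. Of 32 endoplasmic reticulum chaperone genes 16 fell and 0 rose (19 fell and 2 rose adjusted over the list alone), with Hsp90b1 at -0.54 (SE 0.08), Pdia3 at -0.57 (SE 0.09), Sdf2l1 at -1.13 (SE 0.19) and Creld2 at -1.19 (SE 0.20). Tested with camera, the list had an adjusted p of 2.07e-11, with an adjusted p = 0.493 with an estimated correlation and a fry adjusted p of 0.0457. Among 20 cytosolic chaperones 5 fell and 1 rose (7 and 1 adjusted over the list alone): Hsp90aa1 fell by 0.70 (SE 0.14), Dnaja1 by 0.50 (SE 0.09) and Fkbp4 by 0.53 (SE 0.09), and Hspa9 rose by 0.41 (SE 0.08). That list had a camera adjusted p of 0.000569 and an adjusted p = 0.521 with an estimated correlation.

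Secreted and metabolic genes moved both ways in the mean effect. Of 29 acute phase genes 7 rose and 2 fell (9 and 2 adjusted over the list alone), with Serpina3n at 0.58 (SE 0.09), Itih4 at 0.45 (SE 0.08), Il1rn at 1.04 (SE 0.16) and Hamp at 1.62 (SE 0.27). For Hamp the mean rests on the rise at 2 weeks, as its log2 fold change was -0.16 (adjusted p = 0.886) at 8 weeks and 0.20 (adjusted p = 0.901) at 16 weeks. As a list they had a camera adjusted p of 0.00258 and adjusted p = 0.493 with an estimated correlation. Complement genes fell in 2 of 24 cases (6 adjusted over the list alone), C9 and Mbl1 (-0.52, SE 0.14), at a camera adjusted p of 7.79e-07 and an adjusted p = 0.493 with an estimated correlation. Coagulation genes fell in 2 of 25 cases (5 adjusted over the list alone), F11 (-0.71, SE 0.13) and Serpind1 (-0.35, SE 0.07), at a camera adjusted p of 0.0403 and an adjusted p = 0.642 with an estimated correlation. In the growth hormone and IGF list, Ghr (-0.57, SE 0.09), Igf1 (-0.54, SE 0.12) and Igfals (-0.67, SE 0.14) fell and the binding protein gene Igfbp1 rose (0.98, SE 0.24), 4 of 16 genes (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.161). Srebf1, the lipogenic transcription factor gene, fell by 0.82 (SE 0.14) and the citrate lyase gene Acly by 0.68 (SE 0.16), 2 of 26 lipogenesis genes and 2 adjusted over the list alone. The adjusted p by camera was 0.0231, and it was lost at adjusted p = 0.625 with an estimated correlation. Of 30 bile acid genes 2 rose, Cyp39a1 (1.06, SE 0.14) and Abcb4 (0.51, SE 0.06), and 5 fell, Cyp2c70 (-0.51, SE 0.11) and Hsd3b7 (-0.46, SE 0.10) among them (3 and 6 adjusted over the list alone). Tested with camera, the list had an adjusted p of 0.0403, and it was lost at adjusted p = 0.544 with an estimated correlation. In the list of urea cycle and amino acid breakdown Otc (-0.36, SE 0.08) and Hgd (-0.45, SE 0.10) fell, 2 of 43 genes, and 14 fell and 1 rose adjusted over the list alone. As a list they had a camera adjusted p of 3.81e-07, and it was lost at adjusted p = 0.493 with an estimated correlation. Respiratory chain genes fell in 3 of 59 cases (3 adjusted over the list alone; camera adjusted p = 1.73e-09, adjusted p = 0.551 with an estimated correlation), and 0 of 9 adipocyte genes passed (2 fell adjusted over the list alone; camera adjusted p = 0.0451, adjusted p = 0.521 with an estimated correlation). Erythroid genes fell in 2 of 13 cases, Tfrc (-0.98, SE 0.15) and Alas2 (-0.60, SE 0.14), and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000383, adjusted p = 0.493 with an estimated correlation, fry adjusted p = 0.0397). Male-biased liver genes fell in 3 of 29 cases (12 adjusted over the list alone), Selenbp2 (-0.98, SE 0.22), Ugt2b38 (-0.44, SE 0.11) and Alas2, at a camera adjusted p of 6.11e-08 and an adjusted p = 0.493 with an estimated correlation. No cholesterol synthesis gene passed (0 of 25 by edgeR, 0 adjusted over the list alone; median -0.82, camera adjusted p = 2.74e-08, adjusted p = 0.521 with an estimated correlation).

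The mean effect comprised 413 rises and 464 falls, with 3624 genes at an unadjusted p under 0.05. DESeq2 called 654 up and 859 down, limma-voom called 924 genes, and 852 and 841 of the 877 were shared with them; all 877 kept their sign in each fit that left out 1 library. The count was 134 without 2-week asparaginase replicate 1, 230 without 8-week asparaginase replicate 1, 201 without 16-week asparaginase replicate 3, and 1271 without 8-week PBS replicate 1. It was 557, 563 and 338 without 16-week PBS replicates 1, 2 and 3 and 497 without 16-week asparaginase replicate 1. It was 97 without the 3 mixed libraries and with a sex term in adults only, and 87 (65 up and 22 down) without the 2 that held squamous transcripts. Each of these fits keeps 1 library in a group, so the lower counts do not show that the calls came from the libraries left out. No list call, in this or any other comparison, was kept with an estimated correlation.

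**Figure D4:**
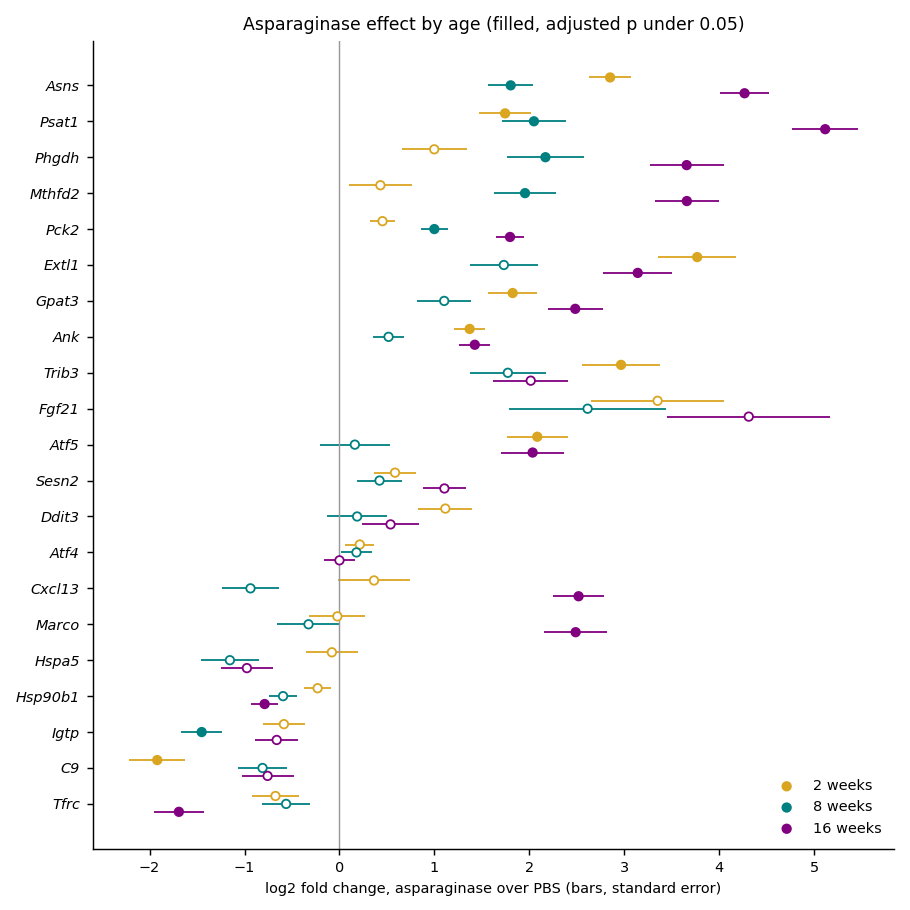
Log2 fold change of asparaginase against PBS ± SE at 2, 8 and 16 weeks for 21 genes, with filled points where the adjusted p is under 0.05. Asns is at 2.85, 1.80 and 4.27 and Psat1 at 1.74, 2.05 and 5.11, filled at every age.

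Differences in the response between ages were tested directly. Between 16 and 8 weeks 2 genes differed, both with a more positive effect at 16 weeks. Cxcl13 differed by 3.46 (SE 0.41, adjusted p = 0.0229). It stood at 17.19, 17.66 and 17.2 CPM in the 16-week asparaginase libraries, at 1.06, 0.48 and 0.62 CPM in those of 8 weeks, and at 0.86 to 4.44 CPM in the adult PBS libraries. The acyltransferase gene Acnat2, higher in every female than in every male library at 16 weeks, differed by 1.43 (SE 0.19, adjusted p = 0.0475). Asns missed the threshold (2.46, SE 0.35, adjusted p = 0.0538). So did Atf5 (1.87, SE 0.49, adjusted p = 0.335), Sesn2 (0.68, SE 0.33, adjusted p = 0.55), Fgf21 (1.7, SE 1.2, adjusted p = 0.689), Ddit3 (0.35, adjusted p = 0.826), Ppp1r15a (0.28, adjusted p = 0.798), Trib3 (0.24, adjusted p = 0.914) and Atf4 (-0.18, adjusted p = 0.834). The 2 calls came down to 0 without 16-week PBS replicates 1 or 3, 8-week asparaginase replicate 1 or 16-week asparaginase replicate 2, and were 8 without 8-week PBS replicate 2 and 7 without 8-week asparaginase replicate 3. They came down to 1 without any of 2-week PBS replicates 1 to 3, 2-week asparaginase replicates 1 or 2, 8-week PBS replicates 1 or 3, or 16-week asparaginase replicate 3. Cxcl13 passed in 13 of the 18 fits that left out 1 library and Acnat2 in 3. DESeq2 called 147 genes and limma-voom 2, and 1517 genes had an unadjusted p under 0.05.

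Between 8 and 2 weeks, and between 16 and 2 weeks, no gene differed by edgeR (0 in each), with 1509 and 1005 genes at an unadjusted p under 0.05, 83 and 107 called by DESeq2 and 1 each by limma-voom. For Asns the difference was -1.05 (SE 0.32, adjusted p = 0.384) between 8 and 2 weeks and 1.42 (SE 0.34, adjusted p = 0.28) between 16 and 2 weeks, and for Atf5 it was -1.92 (SE 0.48, adjusted p = 0.353) and -0.05 (SE 0.45, adjusted p = 0.998). The joint test over the 3 ages called 0 genes by edgeR, 155 by DESeq2 and 1 by limma-voom, with 1529 at an unadjusted p under 0.05. Without 8-week asparaginase replicate 3 the count was 12 for 8 against 2 weeks and 15 for the joint test. Without 2-week PBS replicate 3 the counts were 2 for 8 against 2 weeks, 3 for 16 against 2 weeks and 3 for the joint test; no other library brought them above 3. By camera the effect on cell cycle genes was more positive in adults: 0 of 40 passed over all genes, while 14 and 34 were higher adjusted over the list alone in the 8-week and 16-week differences from 2 weeks. These had camera adjusted p-values of 4.1e-26 and 9.49e-36, with adjusted p = 0.361 and adjusted p = 0.163 with an estimated correlation. The circadian clock list differed between 16 and 8 weeks with a median of -0.66, with 0 of 19 genes past the threshold and 8 lower adjusted over the list alone (camera adjusted p = 2.75e-08, adjusted p = 0.0719 with an estimated correlation, fry adjusted p = 0.0101). At 8 weeks the effect on this list had a median of 0.57 (9 of 19 higher adjusted over the list alone; camera adjusted p = 6.75e-05, adjusted p = 0.258 with an estimated correlation), and at 16 weeks a median of -0.27. Camera gave an adjusted p of 0.00303, and it was lost at adjusted p = 0.358 with an estimated correlation. Cytosolic aminoacyl-tRNA synthetases had a more positive effect at 16 than at 8 weeks by camera (0 of 20 passed and 9 did adjusted over the list alone; adjusted p = 5.97e-09, adjusted p = 0.367 with an estimated correlation). So did the ATF4 and CHOP targets (0 of 41 and 5 adjusted over the list alone; adjusted p = 0.000487, adjusted p = 0.409 with an estimated correlation).

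In PBS mice the change from 2 to 8 weeks was large. The Mup genes, which encode urinary pheromone carriers, made up the largest rises: Mup5 by 8.97 (SE 0.91), Mup13 by 8.65 (SE 1.12), Mup14 by 8.53 (SE 1.06), Mup19 by 8.42 (SE 1.03) and Mup15 by 8.41 (SE 1.04) on the log2 scale, paralogs whose single values are uncertain. The largest falls belonged to pancreatic genes and to genes near or at 0 in adults. The sulfotransferase gene Sult2a6 was at least 193-fold lower and the calcium channel gene Cacna1b at least 122-fold lower at 8 weeks. The ratio of counts at 2 over 8 weeks was 1420 (95% interval 393 to 11700) for the amylase gene Amy2a1, 347 (118 to 1680) for Amy2b and 598 (107 to 23700) for Reg1. Cell cycle genes fell in 37 of 40 cases and rose in 0 (38 fell adjusted over the list alone), with Cdk1 at -3.34 (SE 0.29), Mcm6 at -2.88 (SE 0.30), Ccne2 at -2.19 (SE 0.23) and Mcm3 at -1.80 (SE 0.19). Camera gave an adjusted p of 3.26e-24 and adjusted p = 0.234 with an estimated correlation. Of 24 perinatal liver genes 19 fell, among them the RNA-binding protein gene Igf2bp3 (-6.40, SE 0.37) and the imprinted genes Grb10 (-3.79, SE 0.30) and Cdkn1c (-3.22, SE 0.26), and 2 rose, Scd2 (2.05, SE 0.20) among them (20 and 2 adjusted over the list alone). By camera the adjusted p was 2.98e-08 (adjusted p = 0.234 with an estimated correlation).

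Sex-biased genes changed between 2 and 8 weeks in PBS mice. The comparison is set at an even mix of the labelled sexes, but both 2-week PBS libraries labelled male also hold female transcripts, so that the 2-week side has no purely male library and the balance of the sexes there is not known. Of 29 male-biased genes 25 rose, with the elongase gene Elovl3 at 5.07 (SE 0.52), Susd4 at 3.39 (SE 0.31), C6 at 2.58 (SE 0.24) and Ugt2b38 at 2.05 (SE 0.20) (25 adjusted over the list alone). With camera the adjusted p came to 5.16e-16 (adjusted p = 0.234 with an estimated correlation). Of 31 female-biased genes 19 fell and 3 rose, with Sult2a1 at -7.82 (SE 0.83), the hydroxyacid oxidase gene Hao2 at -5.21 (SE 0.42), Cyp2a22 at -2.88 (SE 0.27) and Fmo2 at -1.94 (SE 0.23) (19 and 6 adjusted over the list alone). The adjusted p by camera was 0.000114 (adjusted p = 0.234 with an estimated correlation). Lipogenesis genes rose in 17 of 26 cases and fell in 0, with Acacb at 3.07 (SE 0.44), Me1 at 2.92 (SE 0.33), Mid1ip1 at 1.7 (SE 0.30) and the citrate carrier gene Slc25a1 at 1.5 (SE 0.27) (17 adjusted over the list alone). Tested with camera, the list had an adjusted p of 6.1e-08 (adjusted p = 0.234 with an estimated correlation). In the NRF2 and glutathione list 22 of 38 rose and 2 fell, with Aox1 at 2.32 (SE 0.32), catalase (Cat) at 1.08 (SE 0.16) and glutathione reductase (Gsr) at 0.76 (SE 0.11) (23 and 2 adjusted over the list alone). As a list they had a camera adjusted p of 1.69e-07 (adjusted p = 0.35 with an estimated correlation). Neutrophil genes fell in 7 of 11 cases, with Ngp at -4.87 (SE 0.70), Ltf at -3.91 (SE 0.60), Mmp8 at -3.71 (SE 0.59) and S100a9 at -2.75 (SE 0.47) (8 adjusted over the list alone). Camera gave an adjusted p of 0.000294 (adjusted p = 0.234 with an estimated correlation). Genes of stellate cells and matrix fell in 14 of 20 cases, with Col3a1 at -3.08 (SE 0.34), Col5a1 at -2.56 (SE 0.24), Reln at -1.72 (SE 0.21) and Tgfbi at -1.04 (SE 0.11) (14 adjusted over the list alone). By camera the adjusted p was 6.51e-08 (adjusted p = 0.234 with an estimated correlation).

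Between 2 and 8 weeks 2394 genes rose and 2743 fell in PBS mice, 6940 genes had an unadjusted p under 0.05, and in 4093 of the 5137 the groups separated completely. DESeq2 called 5085 and limma-voom 5199. The count was 3366 and 2265 without 2-week PBS replicates 2 and 3 and 3388 without 8-week PBS replicate 2, and it was 3243 without the 3 mixed libraries and with a sex term in adults only, a fit that keeps 1 PBS library of 2 weeks. Upper-quartile scaling moved the median of all genes from -0.009 to -0.104 and the split of calls to 1660 up and 3336 down.

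From 2 to 16 weeks 2147 genes rose and 2354 fell in PBS mice (6455 at an unadjusted p under 0.05; 4571 called by DESeq2 and 4551 by limma-voom). Mup5 rose by 9.22 (SE 0.91), Mup13 by 8.84 (SE 1.12), Mup14 by 8.70 (SE 1.06), Mup15 by 8.67 (SE 1.04) and Mup12 by 8.66 (SE 1.05). Sult2a6 was at least 183-fold lower, Cfap44 at least 118-fold, Cacna1b at least 116-fold, the fibrillin gene Fbn2 at least 61.6-fold and the GABA transporter gene Slc6a11 at least 57.7-fold lower. Cell cycle genes fell in 36 of 40 cases (37 adjusted over the list alone; camera adjusted p = 1.19e-24, adjusted p = 0.246 with an estimated correlation) and male-biased genes rose in 25 of 29 (26 adjusted over the list alone). With camera the adjusted p came to 1.44e-17 (adjusted p = 0.246 with an estimated correlation). Of 32 endoplasmic reticulum chaperone genes 15 rose and 1 fell (18 and 1 adjusted over the list alone), with Dnajc3 at 1.05 (SE 0.16), Edem2 at 0.83 (SE 0.15), Sec24d at 0.82 (SE 0.14) and the unfolded protein sensor gene Atf6 at 0.73 (SE 0.16). The adjusted p by camera was 8.03e-07 (adjusted p = 0.564 with an estimated correlation). Serine, glycine and one-carbon genes fell in 11 of 30 cases, with Psat1 at -2.65 (SE 0.34), the glycine decarboxylase gene Gldc at -1.33 (SE 0.26) and Tyms at -0.54 (SE 0.11) (11 adjusted over the list alone). Tested with camera, the list had an adjusted p of 0.0154 (adjusted p = 0.564 with an estimated correlation). The count was 2906 and 1896 without 2-week PBS replicates 2 and 3 and 2162 without 16-week PBS replicate 3, and the groups separated completely in 3894 of the 4501. Upper-quartile scaling moved the median from -0.009 to -0.106 and the split to 1524 up and 2959 down.

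Between 8 and 16 weeks in PBS mice 29 genes rose and 38 fell. The protease inhibitor gene Serpine2 rose by 2.00 (SE 0.32), the signalling inhibitor gene Spry4 by 1.80 (SE 0.24) and the mitotic kinase gene Wee1 by 1.59 (SE 0.29). The fatty acid hydroxylases Cyp4a14 (-2.70, SE 0.39), Cyp4a10 (-1.92, SE 0.34) and Cyp4a31 (-1.7, SE 0.26) and the fatty acid transporter Cd36 (-0.99, SE 0.19) fell, 4 of 44 genes in the list of fatty acid oxidation and PPARA targets and 8 adjusted over the list alone. As a list they had a camera adjusted p of 6.96e-07, and it was lost at adjusted p = 0.706 with an estimated correlation. Fam19a2 (-2.69, SE 0.42), Olig1 (-2.01, SE 0.34) and Spon2 (-1.87, SE 0.35) fell as well. Of 19 circadian clock genes Per2 (1.31, SE 0.21) and Usp2 (1.52, SE 0.29) rose, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.96e-07, adjusted p = 0.172 with an estimated correlation, fry adjusted p = 0.00812). At an unadjusted p under 0.05 there were 2493 genes; DESeq2 called 550 and limma-voom 71. The count ran from 3 without 16-week PBS replicate 3 to 397 without 8-week PBS replicate 3. It was 131, 39 and 41 without 2-week PBS replicates 1 to 3, 41, 27 and 41 without 2-week asparaginase replicates 1 to 3, 29 and 16 without 8-week PBS replicates 1 and 2, and 10 and 17 without 16-week PBS replicates 1 and 2. It was 44, 44 and 43 without 8-week asparaginase replicates 1 to 3 and 34 and 30 without 16-week asparaginase replicates 1 and 3, and the groups separated completely in 58 of the 67.

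Sex differences were compared within each age, males against females. In adults the pattern of sex-biased liver genes was pronounced: the P450 gene Cyp2d9 was higher in males by 3.43 (SE 0.26) at 8 weeks and 4.24 (SE 0.26) at 16 weeks, the complement gene C6 by 3.19 (SE 0.24) and 3.34 (SE 0.25), and the transporter gene Abcg2 by 1.46 (SE 0.11) and 1.35 (SE 0.11). Cyp2b13 was higher in females, at -8.77 (SE 0.48) and -10.88 (SE 0.53), as were Sult2a2 at -8.00 (SE 0.75) and -9.80 (SE 0.89) and Hao2 at -5.69 (SE 0.48) and -6.02 (SE 0.63). At 8 weeks 415 genes were higher in males and 771 in females, and at 16 weeks 145 and 172. At 8 weeks muscle transcripts were also higher in every female library than in every male one, and the library with the most squamous transcripts was female, so part of the 771 can come from other tissues. At both adult ages 103 genes were higher in males and 88 in females, where independent lists would share 3.71 and 8.18, and 0 genes had opposite signs. At 2 weeks no gene differed by sex (0 by edgeR, 1405 at an unadjusted p under 0.05), in a comparison whose labels 3 libraries contradict in part; DESeq2 and limma-voom were not run on it.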

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

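The patterns weighed here and their tests, the comparison with other splits of the same libraries included, were written down after the results had been seen.

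Cxcl13 differed in its response between 16 and 8 weeks by 3.46 (SE 0.41), and Acnat2 by 1.43 (SE 0.19); both stand out as effects that differ between groups of mice. For Acnat2 the 16-week libraries follow sex: it stood at 8.79 CPM in the male PBS library and at 70.95 CPM in the female asparaginase library, and its difference between males and females at that age was -2.35. At 8 weeks the asparaginase libraries did not follow sex, with 13.45 CPM in the female one and 12.68 and 12.77 CPM in the male ones. In the joint comparison of 16 with 8 weeks, 9 of 60 splits gave at least as many genes as the 2 found, and the highest other split gave 61, so chance cannot be excluded and such counts can arise from the structure of the samples.

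The circadian clock list differed in its response between 16 and 8 weeks with a median of -0.66. The 8-week PBS livers stood apart from the other adult livers. The measure was the mean log2 level of the genes that peak with Per1 and Per2, less that of the genes of the opposite phase. It was 2.28, 2.45 and 1.39 in those livers, against 3.65, 3.31 and 3.22 with asparaginase at 8 weeks. At 16 weeks it was 3.51, 3.6 and 3.3 with PBS and 2.91, 3.21 and 3.18 with asparaginase. The 2-week libraries spread further within each group, at 3.13, 0.91 and -0.59 with PBS and 0.88, -0.75 and 0.5 with asparaginase. At 8 weeks the effect was negative in 5 of 5 genes of the opposite phase (Arntl, Npas2, Clock, Cry1 and Nfil3), none of which passed (adjusted p = 0.298, 0.847, 0.685, 0.832 and 0.583), while the genes that peak with Per1 and Per2 had a median of 0.91. A different phase of the clock in PBS and asparaginase livers would give such signs. At 16 weeks only 2 of 5 went opposite to a median of -0.33, which decides nothing. The test against 1 shift of the clock by asparaginase at every age (fry adjusted p = 0.0101) restates the difference that drew attention to the list, and camera lost that difference with an estimated correlation (adjusted p = 0.0719), so such a shift is not excluded. A first form of the test of phase asked for medians of opposite sign at both ages and failed, because at 16 weeks the medians were -0.33 and -0.01; it was replaced by the tests at 8 and at 16 weeks given here after that result was seen. Among the adults the untreated livers of 8 weeks are the ones that differ, so the hour of collection, their age and an effect of the drug all stay open.

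In 3 of the 2-week libraries Xist and Y-linked transcripts occurred together. Taken as shares of the levels in unmixed libraries, the 2 summed to between 0.87 and 1.08, as RNA of a male and a female pup in the same library would give. An animal with 2 X chromosomes and a Y would give a sum near 2 and is ruled out at 1.08. Reads carried over from adult libraries are ruled out by the Mup share, at most 0.58% in these 3.

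Squamous transcripts in 2 of the 3 asparaginase livers at 8 weeks kept nearly the same ratio over 12 markers (SD 0.24 on the log2 scale). Tissue carried in with the liver piece would give this. A programme switched on in only some treated livers could keep such a ratio as well, so the ratio does not decide between them. A squamous programme switched on by asparaginase in every treated liver is ruled out, as only 2 of 9 asparaginase libraries lay above the highest PBS library.

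Other splits of the same mice were too few within an age to exclude chance: the real split gave 70 genes at 2 weeks (highest other 18, 1 of 9 splits at least as large), 59 at 8 weeks (highest other 0, 1 of 9) and 38 at 16 weeks (highest other 15, 1 of 9). For the ages in PBS mice it gave 5137 genes between 8 and 2 weeks (highest other 3, 1 of 10), 4501 between 16 and 2 weeks (highest other 26, 1 of 10) and 67 between 16 and 8 weeks (highest other 0, 1 of 10). For the mean effect no other split came near the real 877 genes (highest other 1, 1 of 60 splits). That is the smallest share 60 splits can give, so chance is unlikely but not excluded. The overlap of 19 (highest other 1, 1 of 60) is no separate test, as most splits called 0 genes at each age. The differences of 8 and 16 weeks from 2 weeks and the joint test over ages had 0 genes each. Nothing is decided there (60 of 60, highest other 2, 15 and 15).

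Counts of lists called by camera are no guide to the treatment. Within ages the real split gave 14 lists at 2 weeks (highest other 21, 8 of 9), 23 at 8 weeks (highest other 19, 1 of 9) and 19 at 16 weeks (highest other 18, 1 of 9). For the ages in PBS mice it gave 18 lists (highest other 21, 5 of 10), 19 lists (highest other 18, 1 of 10) and 19 lists (highest other 20, 3 of 10). In the joint draws it gave 16 lists for 8 against 2 weeks (highest other 22, 25 of 60), 13 for 16 against 2 weeks (highest other 21, 50 of 60), 18 for 16 against 8 weeks (highest other 21, 12 of 60) and 22 for the mean effect (highest other 21, 1 of 60). The 22 lists exceed the highest other split by 1 list, and leaving out a library gives 16 to 22, so this count is not read as an effect of treatment. Taken list by list for the mean effect, other splits gave camera p-values as small as the real one in 11 of 60 cases for the endoplasmic reticulum chaperones, 18 for the heat shock genes, 14 for the ribosomal proteins (smallest other 7.8e-53 against 3.62e-18), 31 for the Kupffer cell genes, 30 for the aminoacyl-tRNA synthetases, 26 for cholesterol synthesis, 23 each for lipogenesis and for B cells, 17 for T and NK cells, 15 for coagulation, 14 for the adipocyte genes, 11 for the respiratory chain, 10 for the pancreatic acinar genes, 7 each for the acute phase genes, the amino acid transporters and the bile acid genes, 6 for the urea cycle list, 5 each for complement and for the male-biased genes and 3 for the interferon response (smallest other 7.91e-30 against 1.39e-22), the real split included; chance cannot be excluded for these. For the ATF4 and CHOP targets no other split was as small (1 of 60, camera value 4.21e-17 against a smallest other of 5.59e-13). For the erythroid genes 2 of 60 splits were as small, another giving 8.84e-06 against the real 0.000111. With 38 lists tested, chance cannot be excluded for either list. Of the joint draws, 22 could not be fitted and were passed over.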

How the results depend on the processing

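The counts of calls depended on the processing more than the directions of the named genes did, and the cause was not tested. The fits without the mixed libraries, which also had a sex term in adults only, keep 1 PBS library of 2 weeks, and those without the squamous libraries keep 1 asparaginase library of 8 weeks, so fewer calls there follow in part from fewer replicates. At 2 weeks 70 genes became 6 with no sex term, 33 with a sex term in adults only, 1 with each age fitted alone, 452 with DESeq2, 169 with limma-voom, 114 with no low-count filter, 0 without the 3 mixed libraries, 30 without the 2 libraries with squamous transcripts, 11 at an adjusted p under 0.01 and 34 with a fold change of at least 2. At 8 weeks 59 became 2 with no sex term, 25 with it shared across ages, 659 with DESeq2 and 445 with no low-count filter. With a fold change of at least 2 they became 33. At 16 weeks 38 became 19 with no sex term, 71 with each age fitted alone, 322 with DESeq2, 83 with no low-count filter and 15 at an adjusted p under 0.01.

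For the effect at 8 against 2 weeks, 0 became 83 with DESeq2, 1 with limma-voom and 2 with no low-count filter. For 16 against 2 weeks, 0 became 107 with DESeq2, 16 with no low-count filter, 3 with a sex term in adults only, and 1 with no sex term, with limma-voom or without the squamous libraries. For 16 against 8 weeks, 2 became 147 with DESeq2, 10 with no low-count filter, 0 with no sex term, without the squamous libraries or at an adjusted p under 0.01, and 1 with one sex term for all ages, upper-quartile normalization, the CPM filter, a sex term in adults only, without the mixed libraries or without Mup genes. For the joint test over ages, 0 became 155 with DESeq2, 28 with no low-count filter, and 1 with one sex term for all ages, limma-voom or a sex term in adults only. For the mean effect, 877 became 528 with no sex term, 1513 with DESeq2, 97 without the mixed libraries, 87 without the squamous ones, 167 at an adjusted p under 0.01 and 94 with a fold change of at least 2. The overlap of 19 became 3 with no sex term, 8 with one sex term for all ages, 150 with DESeq2, 45 with no low-count filter, 1 with each age fitted alone, 0 without the mixed libraries, 9 without the squamous ones, 3 at an adjusted p under 0.01 and 10 with a fold change of at least 2.

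In PBS mice 5137 became 3243 without the mixed libraries, 2705 at an adjusted p under 0.01 and 1993 with a fold change of at least 2 (8 against 2 weeks), and 4501 became 2403 and 1909 under the last 2 settings (16 against 2 weeks). For 16 against 8 weeks 67 became 550 with DESeq2, 171 with no low-count filter, 40 without the squamous libraries, 3 at an adjusted p under 0.01 and 36 with a fold change of at least 2. Camera with an estimated correlation called 0 lists in every comparison, against 14, 23 and 19 at 2, 8 and 16 weeks, 16, 13 and 18 for the differences between ages, 22 for the mean effect and 18, 19 and 19 for the ages. Fry called 2, 1 and 2 lists at 2, 8 and 16 weeks, 0, 0 and 1 for the differences and 6 for the mean effect. In PBS mice it called 15 for 8 against 2 weeks, 17 for 16 against 2 weeks and 1 for 16 against 8 weeks. With no sex term camera called 14 lists at 8 weeks.

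Leaving out each library in turn moved the counts between 0 and 265 at 2 weeks, 0 and 398 at 8 weeks, 5 and 52 at 16 weeks, 0 and 12 for 8 against 2 weeks, 0 and 3 for 16 against 2 weeks, 0 and 8 for 16 against 8 weeks, 0 and 15 for the joint test, 134 and 1271 for the mean effect, and 3 and 29 for the overlap. In PBS mice the ranges were 2265 to 5585, 1896 to 5270 and 3 to 397. The counts of lists ranged from 13 to 16, 15 to 24 and 18 to 24 at 2, 8 and 16 weeks, 12 to 22, 11 to 20 and 16 to 20 for the differences, 16 to 22 for the mean effect and 15 to 20, 15 to 21 and 8 to 21 for the ages.

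Over 246 pairs of a named gene and a comparison, 6216 results under other settings were the same, 1118 weaker, 36 stronger and 72 reversed. Reversals met only genes that had not passed. At 8 weeks Ppp1r15a turned to 0.06 with no sex term, 0.04 with one sex term for all ages and 0.32 without the squamous libraries. At 16 weeks Atf4 turned to -0.04 with one sex term for all ages, to -0.01 with DESeq2, with its size factors or without Mup genes, and to 0 with limma-voom, no low-count filter or without the squamous libraries. For 8 against 2 weeks Fgf21 turned to 0.39 with no sex term and 0.24 without the squamous libraries, Ppp1r15a to 0.11 without the squamous libraries, and Atf4 to 0.14 with no sex term, 0.01 with one sex term for all ages, 0.02 with a sex term in adults only and 0.23 without the squamous libraries. For 16 against 2 weeks Atf5 turned to 0.09 without the mixed libraries, and Ppp1r15a to -0.04, -0.07 and -0.08 with no sex term, one sex term for all ages and a sex term in adults only. For 16 against 8 weeks, without the squamous libraries, Ddit3 turned to -0.34 and Ppp1r15a to -0.09.

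Without each library in turn the reversing genes ranged as follows: Atf4 from -0.13 to 0.50 at 8 weeks, -0.22 to 0.22 at 16 weeks, and -0.34 to 0.30, -0.44 to 0.01 and -0.49 to 0.13 for 8 against 2, 16 against 2 and 16 against 8 weeks. Atf5 ranged from -0.62 to 0.95 at 8 weeks and -0.55 to 0.50 for 16 against 2 weeks, and Ddit3 from -0.27 to 0.64 at 8 weeks, -1.11 to 0.02 for 16 against 2 and -0.16 to 0.85 for 16 against 8 weeks. Fgf21 ranged from -2.05 to 0.82 for 8 against 2 and -0.37 to 2.53 for 16 against 2 weeks, Sesn2 from -0.42 to 0.18 and -0.08 to 1.08 for the same 2, and Trib3 from -0.48 to 0.90 for 16 against 8 weeks. Ppp1r15a ranged from -0.18 to 0.56 at 2 weeks, -0.33 to 0.24 at 8 weeks, and -0.59 to 0.15, -0.32 to 0.42 and 0 to 0.56 for 8 against 2, 16 against 2 and 16 against 8 weeks. No paired analysis was possible because the replicate numbers follow the order of deposition and pair no mice. Depth limits the genes with few counts over a group of 3 libraries, such as those at 0 or with 1 to 3 counts.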

Other observations

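The vomeronasal receptor gene Vmn2r3 was nearly silent in all 9 PBS livers, at most 0.11 CPM, and stood at 22.37, 6.69 and 2.57 CPM in the asparaginase livers of 2 weeks. The asparaginase livers of 16 weeks held 8.37, 1.13 and 1.48 CPM and those of 8 weeks 0.05, 0.43 and 6.89 CPM, so that 8 of the 9 lay above every PBS liver. Of the single ages the gene passed the threshold at 2 weeks only, and it passed in the mean effect (adjusted p = 0.0034).

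Atf4 itself did not pass in the mean effect (0.13, SE 0.09, adjusted p = 0.426), while its targets Asns, Trib3 and Fgf21 rose by 2.97, 2.25 and 3.42.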
